A study of Mus musculus with 6 samples.

How the data were processed

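RNA was extracted from newborn mouse (postnatal day 0) epidermal cells sorted for EpCAM, Sca1 and a high level of α6-integrin. Per the labels' protocols, total RNA was amplified with a kit that starts from nanogram amounts, and sequenced as single reads on an Illumina instrument. The 6 libraries were assigned to control (3) or triple knockout of *Eed*, *Ring1* and *Rnf2* (3) from their titles and genotype labels. The labels number replicates 1 to 3 in each group but do not say that they came from separate animals, so p-values measure only the spread between these libraries, which may be partly technical. By *Xist* and Y-linked genes each group held libraries of both sexes, so the libraries of a group did not all come from a single animal. No pair of libraries held an identical value above 0 for any gene.

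The deposited table holds a normalized count per gene and library, named so per the file headers and treated here as a signal, not as raw counts. Per the submitters' processing notes, kallisto 0.42.5 and DESeq2 were used; which annotation, strand setting and options is not given in the sources used here. Kallisto assigns reads to transcripts by estimation, so genes with near-identical copies, such as histone, stefin, serpin, keratin 6 and class I and II histocompatibility genes, can exchange reads, and overlapping or antisense genes cannot be told apart where strand was not used. The value of 1 read was taken as the most frequent low value in each library (0.716 to 1.31), which gives about 17.8 M to 37.7 M assigned reads per library. Of values up to the worth of 20 reads, only 25.9% to 42.7% were whole multiples to within 0.01 of a read. Whole reads were therefore not recovered, no count model was run, and neither exact depth nor counting intervals are given. At these depths, genes at a few normalized counts rest on a handful of reads, and an exact 0 can be a failed estimate.

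Gene coordinates come from the deposited table. Of its 38258 genes, 38243 identifiers were found in GENCODE M21, and 37652 (98.4%) had coordinates and strand identical to that annotation of GRCm38. The build is named from this match, since the sources used here do not give it. GC content and transcript length, from the same annotation, were available for 99.98% of tested genes.

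Values were analysed as log2(normalized count + 1). Genes with a mean normalized count of at least 10 over the 6 libraries (23006) were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust empirical Bayes, no covariate, and Benjamini-Hochberg adjustment with a threshold of 0.05. The targeted genes were also given an exact two-sided permutation test over the 20 assignments of libraries to groups. Lists of genes were tested with camera at a preset inter-gene correlation of 0.01, two-sided, with p-values adjusted over the 30 lists, and again with an estimated correlation. The related fry test, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes, gave an adjusted p below 0.05 for 19 lists.

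The groups, tests, lists and alternatives were fixed before the data were examined. The lists covered untargeted Polycomb subunits, Hox genes, developmental transcription factors of other tissues, secreted morphogens, Merkel cell, basal progenitor, spinous, cornified envelope, stress keratin and alarmin, hair follicle, simple epithelium and endoderm, neuronal, germline, cyclin-dependent kinase inhibitor, p53 target, proliferation, mesenchymal transition, imprinted, interferon response, melanocyte, fibroblast, endothelial, leukocyte and Langerhans cell, skeletal muscle, adipocyte, Schwann cell, erythroid, immediate early and dissociation, sex-linked and mitochondrially encoded genes. Some genes stand in more than 1 list. The genes named in the text are the targets, the 12 largest rises and 12 largest falls among called genes with a mean of at least 50 and no overlap between groups (leaving out predicted genes and clone names), up to 6 called members of each list with the smallest p and up to 4 of its highest-expressed members that did not pass, and any Hox gene. Some genes that this rule names are not reported here.

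The alternatives were pseudocounts of 0.5 and 5, no filter or a mean of at least 50, trimmed-mean factors computed on the deposited values, quantile normalization, limma without trend or robust estimation, the replicate number as a block, an estimated correlation in camera, and leaving out each library in turn. Sex of the pup as a covariate, read from *Xist* and Y-linked genes, and removal of GC content and transcript length per library with splines were added after the data had been seen. The procedure was tested on simulated data for the comparison of the libraries labelled triple knockout with control, with 23006 genes of which 200 were changed. It recovered 20%, 72%, 94% and 100% of genes changed 1.5, 2, 4 and 8-fold, with 7 false calls among 150. It called the planted list and 0 of 29 random lists. The simulation changed 200 genes and used a dispersion of 0.0218 for all, whereas 35.8% of genes were called in the data. Its genes were drawn independently, whereas estimated inter-gene correlations ranged from −0.0583 to 0.85 over the lists. These rates therefore do not carry over to the data.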

Results

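Gene expression was measured by RNA-seq in epidermal progenitor cells of newborn mice. Cells of the interfollicular epidermis of the back were sorted for EpCAM, Sca1 and a high level of α6-integrin, surface proteins that together mark the basal layer. The 6 libraries fall into 3 labelled control and 3 labelled as triple knockout of *Eed*, *Ring1* (Ring1a) and *Rnf2* (Ring1b). Eed is a core subunit of Polycomb repressive complex 2, which methylates histone H3, and Ring1a and Ring1b are the ubiquitin ligases of Polycomb repressive complex 1, which modifies histone H2A. The comparison asks how the transcriptome of these cells differs when both complexes are disrupted together. The deposited normalized counts summed to between 21896285 and 29805729 per library, which corresponds to roughly 17.8 M to 37.7 M assigned reads. Ribosomal RNA genes, mitochondrial ones included, held 23.5%, 22.5% and 36.6% of the normalized count in controls 1, 2 and 3. They held 27.6%, 29.4% and 31.4% in the libraries labelled triple knockout. Values below are normalized counts as mean ± SD (n = 3 libraries per group), and log2 changes are libraries labelled triple knockout minus control on the log2(normalized count + 1) scale, ± SE, which understates the change of low genes.

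The targeted genes were examined first, because they test the labels, and they did not all follow them. *Ring1* (ENSMUSG00000024325.8, GRCm38 chromosome 17, 34020792 to 34024680) was higher, not lower, in the libraries labelled triple knockout. Its normalized counts were 11.8, 8.72 and 23.1 in the controls and 67.7, 104 and 112 in the libraries labelled triple knockout, a log2 change of 2.70 ± 0.40 (limma adjusted p = 0.000759). *Eed* (ENSMUSG00000030619.9, chromosome 7, 89954654 to 89980983) was lower, with 714, 1015 and 778 in the controls and 381, 604 and 441 in the libraries labelled triple knockout, a log2 change of −0.82 ± 0.21 (limma adjusted p = 0.0144). *Rnf2* (ENSMUSG00000026484.13, chromosome 1, 151458004 to 151500955) did not pass the test, with 739, 875 and 1288 against 783, 922 and 694 and a log2 change of −0.24 ± 0.22 (limma adjusted p = 0.417). Exact two-sided permutation tests gave p = 0.1 for *Ring1* and *Eed* and p = 0.5 for *Rnf2*, where 0.1 is the smallest p that 3 against 3 libraries allow. The *Eed* call was lost after removal of GC content and transcript length (log2 change −0.39, limma adjusted p = 0.192), without control replicate 2 (−0.67, limma adjusted p = 0.0523), and without labelled knockout replicate 1 (−0.68, limma adjusted p = 0.0615) or 3 (−0.78, limma adjusted p = 0.0543). These are sums over all transcripts of a gene, and the sources used here do not say which exons were deleted, so RNA from outside a deleted part would check nothing. Because *Ring1* goes against the labels, every direction below is that of the libraries labelled triple knockout relative to the libraries labelled control.

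**Figure D1:**
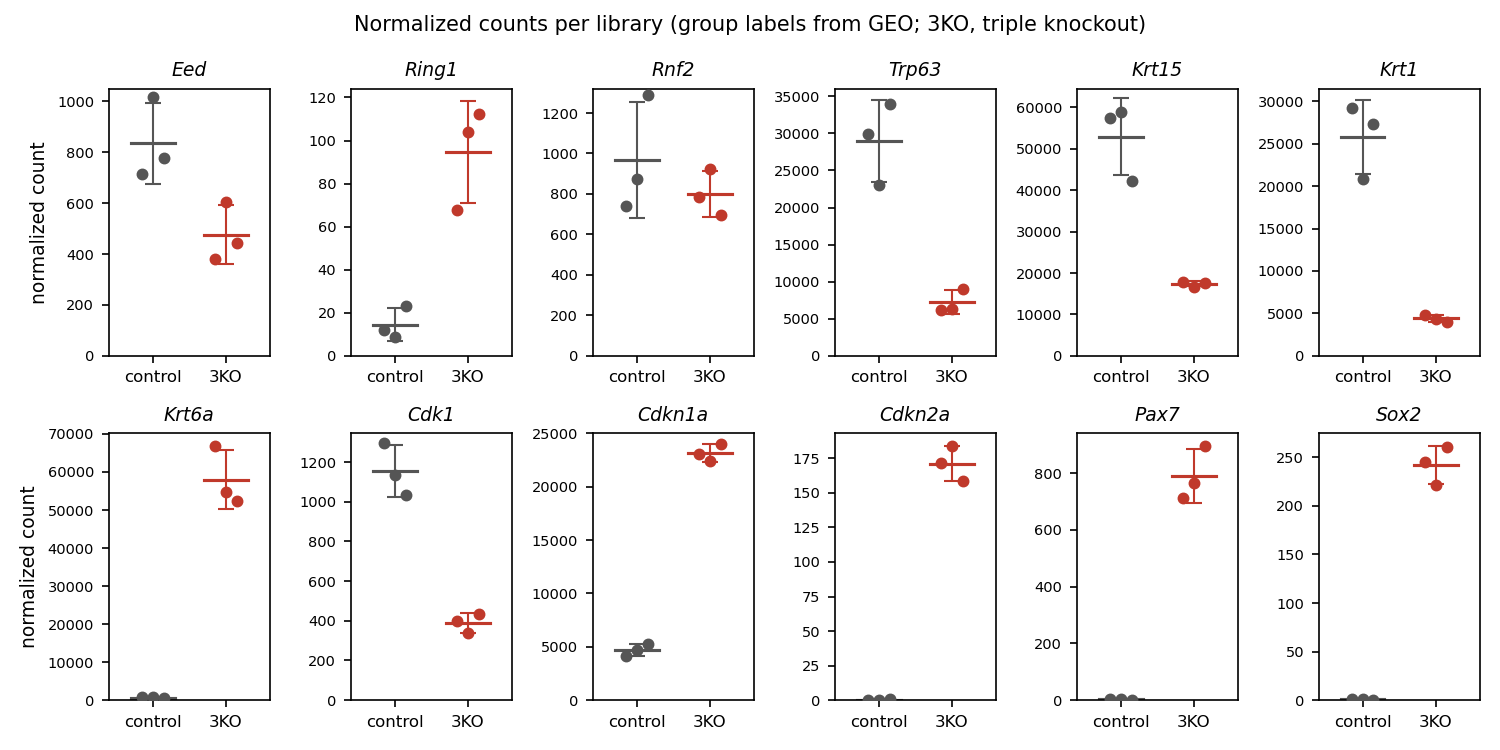
Normalized counts of 12 genes in each library (points), with group mean (horizontal line) and SD (error bar), for control and labelled triple knockout (3KO) libraries, n = 3 each. *Ring1* lies higher in the labelled knockouts (mean 94.6 against 14.6), *Trp63*, *Krt15*, *Krt1* and *Cdk1* lie lower, and *Krt6a*, *Cdkn1a*, *Cdkn2a*, *Pax7* and *Sox2* lie higher with no overlap between the groups.

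The libraries labelled triple knockout expressed many developmental regulators that control epidermal progenitors hardly expressed (85 of 94 tested developmental transcription factors rose). By limma, 18 of 31 cornified envelope genes were higher and 6 lower, and 26 of 40 basal progenitor and 37 of 42 proliferation genes were lower. The camera calls of these 3 lists were lost with an estimated correlation (adjusted p = 0.179, 0.261 and 0.179). Of 23006 genes tested, 4726 were higher and 3516 lower (limma, adjusted p below 0.05), and 5425 of these changed at least 2-fold, 3574 upwards and 1851 downwards. Changes of at least 16-fold were 569 upwards and 46 downwards. The groups did not overlap for 11289 genes (49.1%), where chance gives 10%. Of the calls, 57.3% were higher. Quantile normalization moved the median of all genes by −0.18 on the log2 scale and gave 4177 higher and 4974 lower genes, so that 45.7% of calls were higher.

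The steepest rises were in genes that were close to 0 in the controls. *Stra6*, the cell-surface receptor for retinol uptake, rose from 1.54 ± 0.893 to 2388 ± 70.1. The homeobox gene *Barx1* rose from 0.6696 ± 1.16 to 762 ± 74.7. *Sall3*, a zinc-finger transcription factor, rose from 0.771 ± 0.685 to 869 ± 109. *Ecel1*, a membrane peptidase, rose from 1.52 ± 1.39 to 1039 ± 349, and *Cldn6*, a tight-junction claudin of embryonic epithelia, from 7.08 ± 3.18 to 3023 ± 456. *Chrna4*, a nicotinic acetylcholine receptor subunit, rose from 0.298 ± 0.516 to 397 ± 50.2 and *Spink12* from 1.03 ± 0.9999 to 548 ± 56.7. *Fezf1*, a forebrain transcription factor, and *Psca* were listed at 0 in all control libraries and reached 299.7 ± 24.2 and 299.7 ± 67.8. Among the steepest falls, *Cyp4b1*, a cytochrome P450, fell from 1059 ± 293 to 5.95 ± 1.77 (log2 change −7.25 ± 0.31) and *Arhgap25* from 1165 ± 225 to 27.1 ± 4.84. *Gdpd2* fell from 1493 ± 326 to 39.6 ± 9.27, *Pik3c2g* from 208 ± 63.7 to 2.84 ± 2.46 and *Serpinb7* from 219 ± 108 to 3.83 ± 3.24. *Il22ra2*, the soluble interleukin-22 receptor, and *Krt25*, an inner root sheath keratin, stood at 223 ± 123 and 126 ± 82.1 in controls and were listed at 0 in all libraries labelled triple knockout, and *Krt71*, another inner root sheath keratin, fell from 102 ± 69.9 to 1.37 ± 1.33. *Clca3a2*, *Serpina3b*, *Stfa1* and *Stfa3* were also among the 12 largest falls (*Clca3a2* fell from 6875 ± 1114 to 37.4 ± 9.83), but belong to families of near-identical copies between which reads can be divided wrongly. All of these genes passed the limma test.

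Transcription factors that direct the development of other tissues rose almost as a block. Of 94 tested members of that list, 85 rose, 2 fell and 7 did not pass, with a median log2 change of 4.39 (86 rose adjusted over the list alone). The filter used the mean of all 6 libraries, so genes near 0 in controls were tested only where labelled knockouts were high. Without the filter 91 rose and 2 fell of 111, with a median of 3.74. *Sim2* rose from 1.92 ± 0.831 to 582 ± 84.2. *Dmrt3* rose from 0.334 ± 0.579 to 516 ± 83.96, and *Pitx1*, a hindlimb and pituitary factor, from 3.74 ± 1.92 to 747 ± 119. *Pax7*, a factor of muscle progenitors, rose from 2.498 ± 2.16 to 789.9 ± 95.3, and *Six3*, an eye and forebrain factor, from 12.03 ± 1.08 to 465 ± 64.1. *Gata6*, an endoderm and heart factor, rose from 18.9 ± 2.09 to 477 ± 26.5, and *Wt1*, a kidney and gonad factor, from 15.4 ± 4.001 to 713 ± 85.4. *Irx1*, already expressed in control cells, did not pass (709 ± 412 against 603 ± 85.7, limma adjusted p = 0.857). The list stood above other genes by camera (adjusted p = 1.43e-28), also with an estimated correlation (adjusted p = 0.0374). Markers of some other cell types rose in the same libraries, with 8 of 12 melanocyte genes, 7 of 11 Schwann cell genes and 14 of 20 Merkel cell genes higher. Across 91 markers of fibroblasts, endothelium, leukocytes, muscle, fat and erythroid cells the median log2 change was 0.02, and between −0.30 (without control replicate 1) and 0.39 (without control replicate 3) when single libraries were left out.

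Among 38 tested Hox genes, which set position along the body axis, 21 rose, 7 fell and 10 did not pass (22 rose adjusted over the list alone). All 15 tested genes of paralog groups 9 to 13 rose, with a median log2 change of 6.53, whereas of the 23 in groups 1 to 8, 6 rose and 7 fell (median −0.11). In groups 1 to 8, 3 rose and 9 fell of 22 after removal of GC content and transcript length, 3 rose and 6 fell of 18 with a mean of at least 50, and the median lay between −0.36 and 0.10 over all alternatives. This division was chosen after the values were seen. Most genes of groups 9 to 13 stood near 0 in controls, so they passed the filter only through the labelled knockouts and could hardly fall. In groups 1 to 8 *Hoxd1*, *Hoxd3* and *Hoxd4*, with control means of 0, 8.57 and 4.77, also rose. Paralog group and starting level are therefore confounded in part. *Hoxd13* rose from 1.52 ± 1.64 to 1065 ± 193. *Hoxd11* rose from 2.11 ± 0.9495 to 734 ± 117, *Hoxa10* from 0.701 ± 1.21 to 300.2 ± 25.5 and *Hoxc10* from 5.75 ± 8.14 to 623 ± 82.99, and *Hoxc11*, listed at 0 in all control libraries, reached 221 ± 29.5. In the other direction, *Hoxa7* fell from 1504 ± 238 to 553 ± 49.9 (log2 change −1.43 ± 0.16) and *Hoxa2* from 343 ± 44.96 to 75.4 ± 12.02. By cluster, all 8 tested Hoxd genes rose, against 6 of 9 Hoxc (1 lower), 4 of 11 Hoxa (5 lower) and 3 of 10 Hoxb genes (1 lower). *Hoxb5* (185 ± 19.6 against 233 ± 22.8, limma adjusted p = 0.211) did not pass. The list passed camera (adjusted p = 0.000422) but not with an estimated correlation (adjusted p = 0.134).

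**Figure D2:**
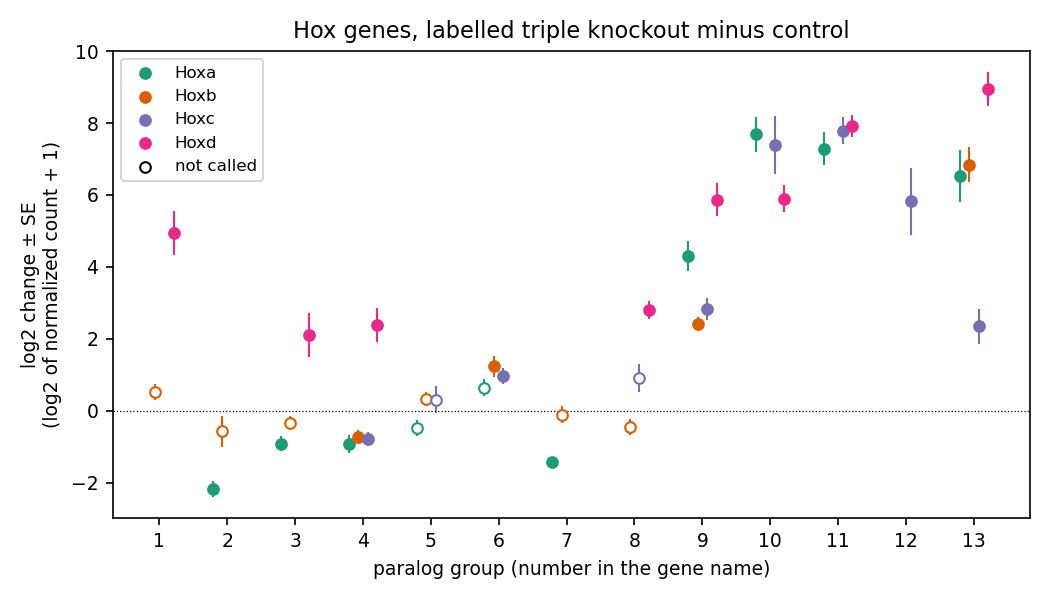
Log2 change (log2 of normalized count + 1, libraries labelled triple knockout minus control, ± SE) of 37 Hox genes against paralog group, coloured by cluster, with open circles for genes that did not pass the limma test. All 15 genes of groups 9 to 13 lie above 0, and the 6 plotted genes that fell lie in groups 2 to 7.

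Genes of simple epithelia and endoderm rose, 21 of 24 tested with 1 lower and a median log2 change of 4.10 (camera adjusted p = 7.61e-12; adjusted p = 0.0728 with an estimated correlation). With no filter on low values 25 of 35 rose and 1 fell, with a median of 2.28. The simple-epithelial keratins *Krt7*, *Krt18* and *Krt19* rose from 171 ± 40.4 to 2816 ± 116, 27.6 ± 14.9 to 1352 ± 132 and 21.1 ± 13.8 to 1409 ± 86.2. The intestinal and renal sodium-glucose transporter *Slc5a1* rose from 7.76 ± 1.098 to 832 ± 40.6. Of 20 Merkel cell genes, 14 rose and none fell by limma, with 2 lower at an unadjusted p below 0.05 (camera adjusted p = 4.66e-05; adjusted p = 0.0728 with an estimated correlation). Of 33 unfiltered Merkel cell genes 17 rose and 0 fell, and the median log2 change went from 2.35 to 1.51. With quantile normalization or sex as a covariate 2 Merkel cell genes fell, and 1 fell after removal of GC content and transcript length or without control replicate 1 or 3. The Merkel cell transcription factors *Sox2* and *Isl1* rose from 0.799 ± 0.701 to 242 ± 19.4 and from 2.802 ± 1.82 to 151 ± 32.9, whereas *Penk* (737 ± 505 against 522 ± 108, limma adjusted p = 0.573) did not pass. Neuronal genes were higher for 24 of 36 and lower for 1 (25 and 2 adjusted over the list alone; camera adjusted p = 3.55e-08; adjusted p = 0.0374 with an estimated correlation). *Dpysl3*, a protein of growing axons, rose from 148 ± 59.3 to 3303 ± 200.3. *Map2*, a dendritic microtubule protein, rose from 66.4 ± 22.2 to 565 ± 122, and *Slc32a1*, the vesicular transporter of inhibitory transmitters, was listed at 0 in all controls and reached 191 ± 43.4. Melanocyte genes (8 of 12 higher, 1 lower; 9 higher adjusted over the list alone) passed camera with adjusted p = 0.0036 and had adjusted p = 0.198 with an estimated correlation and 0.071 for members with a mean of at least 50. *Tyrp1*, a melanin synthesis enzyme, rose from 6.897 ± 5.17 to 155 ± 16.5 and *Dct* from 118 ± 5.82 to 389.8 ± 111. Schwann cell genes (7 of 11 higher, 1 lower; 8 higher adjusted over the list alone) had camera adjusted p = 0.00687, adjusted p = 0.149 with an estimated correlation and 0.154 for members with a mean of at least 50. Of 15 unfiltered Schwann cell genes 7 rose and 1 fell, and the median log2 change went from 1.99 to 1.17. The neural crest factors *Foxd3* and *Sox10* rose from 2.11 ± 2.602 to 95.99 ± 32.5 and 3.94 ± 3.17 to 44.1 ± 13.8, while the receptor *Erbb3* fell from 3853 ± 401 to 2364 ± 228. Of 20 germline genes, 7 rose and 2 fell (camera adjusted p = 0.0461; adjusted p = 0.181 with an estimated correlation). *Tdrd1*, a piRNA pathway gene, rose from 256 ± 106 to 869 ± 171 and the synaptonemal complex gene *Sycp1* fell from 73.997 ± 4.24 to 24.03 ± 11.6. The germline call was lost without control replicate 1 (camera adjusted p = 0.0651) or 3 (0.0513) and without labelled knockout replicate 1 (0.118), 2 (0.082) or 3 (0.152, with 4 members higher), and for members with a mean of at least 50 (0.0741), while with no filter 11 rose and 1 fell of 45.

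**Figure D3:**
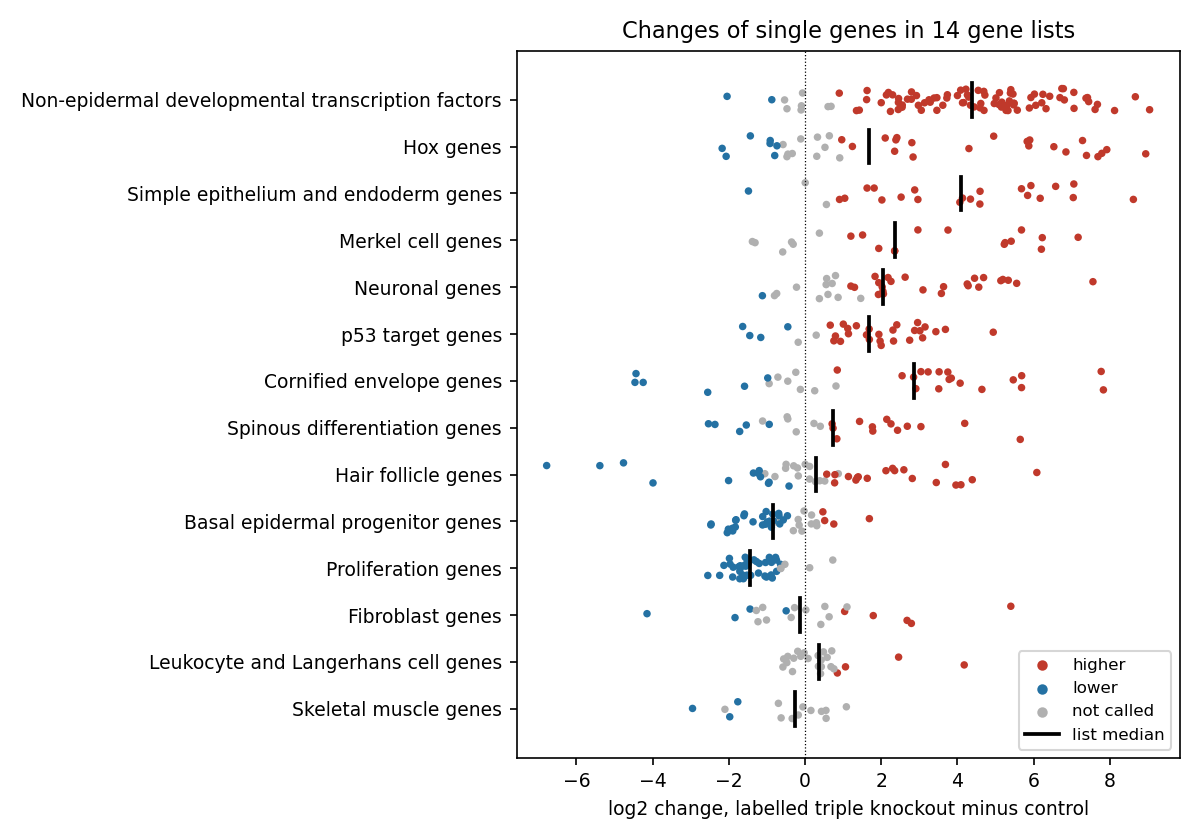
Log2 change (libraries labelled triple knockout minus control) of each tested gene in 14 gene lists, red for higher, blue for lower and grey for not called by limma, with the list median as a black line. Developmental transcription factors (median 4.39) and simple-epithelium genes (4.10) lie to the right, and proliferation genes (−1.46) and basal progenitor genes (−0.84) to the left.

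Basal progenitor genes moved the other way. Of 40 tested, 26 fell and 4 rose (24 and 2 without labelled knockout replicate 3), with a median log2 change of −0.84 (camera adjusted p = 1.87e-07; adjusted p = 0.261 with an estimated correlation). The median was −1.27 after removal of GC content and transcript length. *Trp63*, the master transcription factor of stratified epithelia, fell from 28984 ± 5557 to 7206 ± 1615 (log2 change −2.01 ± 0.19). Among genes of the attachment to the basement membrane, *Col17a1* fell from 39558 ± 2043 to 9686 ± 1526. *Lamb3* fell from 5204 ± 537 to 1459.8 ± 57.5. The basal keratin *Krt15* fell from 52924 ± 9213 to 17407 ± 598. *Cdh1* (22066 ± 1725 against 24813 ± 685, limma adjusted p = 0.269) and *Perp* (24808 ± 2449 against 21894 ± 1893, limma adjusted p = 0.303), genes of cell-cell adhesion, did not pass.

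Genes of later epidermal differentiation changed in both directions. Of 31 tested cornified envelope genes, 18 rose and 6 fell, with a median log2 change of 2.85 (19 and 6 adjusted over the list alone; camera adjusted p = 0.000218; adjusted p = 0.179 with an estimated correlation). With no filter on low values 20 rose and 12 fell of 53, with a median of 0.61, and with a mean of at least 50 15 rose and 3 fell of 24. *Spink5*, a protease inhibitor of the upper epidermis, rose from 144 ± 31.7 to 7335 ± 65.5. *Cnfn* rose from 8.53 ± 3.096 to 2092 ± 228, the transglutaminase *Tgm1* from 276 ± 29.6 to 2594 ± 224 and *Sprr1a* from 223 ± 96.004 to 9322 ± 435, while the major envelope protein gene *Lor* (136 ± 60.5 against 225 ± 26.3, limma adjusted p = 0.0718) did not pass, and passed without control replicate 1 (log2 change 1.14, limma adjusted p = 0.0134). Spinous genes split, with 13 of 24 higher and 5 lower (13 and 7 adjusted over the list alone), and did not pass camera (adjusted p = 0.0726). The spinous keratin *Krt1* fell from 25769 ± 4356 to 4416 ± 392.2 (log2 change −2.53 ± 0.15) and the claudin *Cldn1* from 17598 ± 2033 to 5343 ± 242, whereas *Grhl3*, a transcription factor of barrier formation, rose from 408 ± 44.6 to 2632 ± 339.5 and *Calml3* from 22.6 ± 5.94 to 1156 ± 22.6. The spinous list passed camera with quantile normalization (adjusted p = 0.00833), with sex as a covariate (0.0438) and with no filter on low values (0.0417). Stress keratins and alarmins were 7 higher and 3 lower of 16 (camera adjusted p = 0.105, and 0.0314 after removal of GC content and transcript length). The wound-associated keratins *Krt6a*, *Krt6b* and *Krt17* rose from 681 ± 194 to 57998 ± 7772, 39.1 ± 29.6 to 4218 ± 961 and 3238 ± 1154 to 24492 ± 2332, although *Krt6a* and *Krt6b* are near-identical and can share reads, and *Defb4*, listed at 0 in all controls, reached 89.996 ± 16.2. Hair follicle genes were 19 higher and 12 lower of 45 (20 and 12 adjusted over the list alone; camera adjusted p = 0.46), and their median log2 change of 0.28 became −0.21 after removal of GC content and transcript length and 0.52 with a mean of at least 50, and was 0.12 and 0.14 without labelled knockout replicates 2 and 3. *Krt79*, a keratin of the hair canal, rose from 585 ± 437 to 33530.5 ± 1802, and *Lgr6* (3973 ± 589 against 4055 ± 1076, limma adjusted p = 0.988) did not pass.

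Cell-cycle genes were lower in the libraries labelled triple knockout. Of 42 proliferation genes, 37 fell and none rose by limma (38 fell adjusted over the list alone, and 0 were higher at an unadjusted p below 0.05), with a median log2 change of −1.46 (camera adjusted p = 5.71e-16; adjusted p = 0.179 with an estimated correlation). Without control replicate 1, 1 was higher. The mitotic kinase *Cdk1* fell from 1156 ± 132 to 389.5 ± 48.8. Cyclin B1 (*Ccnb1*) fell from 1372 ± 167 to 346 ± 40.5, and the replication helicase subunit *Mcm6* from 1515 ± 115 to 410.1 ± 41.7. *Foxm1*, a transcription factor of mitotic genes, fell from 2473 ± 626 to 417 ± 72.96. *Tk1* (835 ± 39.9 against 909 ± 51.4, limma adjusted p = 0.512) did not pass. Of 8 cyclin-dependent kinase inhibitors 4 rose, 3 fell and 1 did not pass (camera adjusted p = 0.45). *Cdkn2a*, the INK4a/ARF locus and a textbook Polycomb target, rose from 0.329 ± 0.5698 to 171 ± 12.7. *Cdkn2b* rose from 5.51 ± 2.39 to 277 ± 59.7 and *Cdkn1a* (p21) from 4699 ± 541 to 23171 ± 805, while *Cdkn1b* and *Cdkn2c* fell from 972 ± 65.3 to 579 ± 76.4 and 163 ± 11.1 to 74.2 ± 13.6. Genes induced by p53 rose for 26 of 32 and fell for 4, with a median log2 change of 1.69 (camera adjusted p = 1.07e-08; adjusted p = 0.134 with an estimated correlation). *Zmat3* rose from 1159 ± 191 to 10245 ± 1245. *Plk3* rose from 207 ± 25.5 to 1607 ± 113 and *Pmaip1* (Noxa), a cell-death gene, from 534 ± 41.3 to 3605 ± 498.

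Secreted morphogens were 15 higher and 8 lower of 36 (16 and 8 adjusted over the list alone; camera adjusted p = 0.105). Without control replicate 1 or labelled knockout replicate 1, 5 were lower. Their median log2 change of 0.66 became −0.02 for the 25 members with a mean normalized count of at least 50, 0.42 with quantile normalization and 0.04 after removal of GC content and transcript length, and with no filter the list passed (camera adjusted p = 0.0417). *Wnt5a* rose from 103 ± 69.03 to 1766 ± 238 and *Wnt11* from 28.8 ± 10.5 to 492 ± 94.3, and *Wnt16* fell from 852 ± 106 to 140.1 ± 20.6. Imprinted genes rose for 18 of 33 and fell for 3 (20 and 4 adjusted over the list alone), with a median log2 change of 1.29 (camera adjusted p = 5.5e-05; adjusted p = 0.179 with an estimated correlation). The maternally expressed RNAs *Meg3* and *Rian* of the Dlk1-Dio3 region rose from 569 ± 123 to 8966 ± 1317 and 301 ± 22.3 to 3665 ± 297. *Zdbf2* and *Grb10* rose from 355 ± 127 to 5200.3 ± 85.97 and 843 ± 297 to 4631 ± 272, whereas *Gnas* (10374 ± 3095 against 10300.4 ± 1340.0, limma adjusted p = 0.95) did not pass. Of 37 Polycomb subunits other than the targets, 13 rose and 7 fell, with a median log2 change of 0.03 that became −0.06 with quantile normalization and lay between −0.11 (without control replicate 2) and 0.19 (without labelled knockout replicate 1) when single libraries were left out (camera adjusted p = 0.458). The lower members numbered 4 without control replicate 1 or 2 and 3 without labelled knockout replicate 1 or 2. *Bcorl1* rose from 180.2 ± 14.6 to 771 ± 158. *Phc1* rose from 396 ± 31.5 to 877 ± 26.05, and *Suz12*, another core subunit of Polycomb repressive complex 2, did not pass (2383 ± 199 against 1974 ± 159, limma adjusted p = 0.137). Genes of mesenchymal transition were 12 higher and 1 lower of 23 (camera adjusted p = 0.0461; adjusted p = 0.756 with an estimated correlation). Fibronectin (*Fn1*) rose from 5179 ± 1144 to 13800.0 ± 1479 and *Snai2*, a transcription factor of both basal and mesenchymal cells, fell from 2764 ± 379.6 to 930.2 ± 181. The mesenchymal call was lost with a mean of at least 50 (camera adjusted p = 0.109), after removal of GC content and transcript length (0.198), and without control replicate 1 (0.182) or 2 (0.106) or labelled knockout replicate 2 (0.0824) or 3 (0.0761).

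Markers of other cells, which the sort may not have excluded in full, and of tissue handling were examined next. Fibroblast genes were 5 higher and 4 lower of 20 (median log2 change −0.13, mean 0.16, camera adjusted p = 0.903), with 1 lower without control replicate 2 or labelled knockout replicate 1 or 3 and 2 lower without labelled knockout replicate 2. When single libraries were left out the fibroblast median lay between −0.36 (without control replicate 1) and 0.33 (without control replicate 3), and it was also above 0 without labelled knockout replicate 1 (0.08). *Postn* fell from 15743 ± 3290.2 to 902 ± 258 and *Fstl1* rose from 2125 ± 1206 to 13347 ± 1493, while the collagen *Col1a1* (4968 ± 4651 against 3826 ± 935, limma adjusted p = 0.981) did not pass. Endothelial genes were 3 higher and 1 lower of 17 (camera adjusted p = 0.299, median 0.59, and −0.03 with quantile normalization). The endothelial median was 0.24, 0.29 and 0.92 without control replicates 1, 2 and 3 and 0.25 without labelled knockout replicate 3. *Prox1* and *Flt1* rose from 49.2 ± 25.1 to 1022 ± 121 and 91.5 ± 7.69 to 722 ± 91.8, but *Pecam1* (234 ± 65.4 against 248 ± 62.9, limma adjusted p = 0.84) did not pass. Leukocyte and Langerhans cell genes were 4 higher of 24 with none lower by limma (3 higher adjusted over the list alone, and 0 lower at an unadjusted p below 0.05; camera adjusted p = 0.293). They were 3 higher with quantile normalization, with limma without trend or robust estimation, or with sex as a covariate. The count was also 3 when any single library other than control replicate 3 was left out, and 5 after removal of GC content and transcript length. The class II antigen-presentation genes *H2-Eb1* and *H2-Ab1* rose from 40.6 ± 14.5 to 732 ± 143 and 148 ± 87.9 to 737 ± 125, and their invariant chain *Cd74* (386 ± 178 against 585 ± 105, limma adjusted p = 0.109) passed without control replicate 3 (log2 change 1.03, limma adjusted p = 0.0021). Control replicate 3 carried the largest ribosomal and mitochondrial shares, which both include the mitochondrial ribosomal RNA genes. Without it 11 leukocyte genes were higher of 23 (camera adjusted p = 0.0107), 6 endothelial genes were higher of 15 (0.0474) and 8 fibroblast genes were higher of 20. Of the 15 mitochondrially encoded genes 6 were then higher (camera adjusted p = 0.0192). With all libraries none of these 15 passed limma and 1 was higher at an unadjusted p below 0.05 (camera adjusted p = 0.458). The mitochondrially encoded list also passed after removal of GC content and transcript length (0.0219). Skeletal muscle genes were 3 lower of 14 with none higher by limma, and 0 higher at an unadjusted p below 0.05 (camera adjusted p = 0.18, and 5 lower with quantile normalization), adipocyte genes 1 higher of 10 (0.458; *Pparg* rose from 30.1 ± 19.995 to 104 ± 32.3), and erythroid genes 1 lower of 6 (0.458; *Alas2* fell from 101 ± 12.9 to 46.03 ± 3.12; 2 higher without control replicate 3). Interferon response genes were 2 higher and 6 lower of 31 (1 and 6 adjusted over the list alone; camera adjusted p = 0.18, and 0.0464 without control replicate 1), with *Irf1* lower, from 1794 ± 668 to 275 ± 28.1, and without control replicate 3 they were 5 higher and 5 lower. Immediate early and dissociation genes, which respond to tissue handling, were 10 higher and 8 lower of 27 (10 and 9 adjusted over the list alone; camera adjusted p = 0.955). They were 9 higher and 4 lower without labelled knockout replicate 1, 6 higher without labelled knockout replicate 2 or 3, and passed camera as lower, with 7 higher and 10 lower, after removal of GC content and transcript length (adjusted p = 0.0314). The heat-shock gene *Hsph1* rose from 351 ± 123 to 1850.1 ± 113, *Cyr61* fell from 15213 ± 4151 to 2737 ± 218, and *Fos* (13698 ± 2851 against 13601 ± 1378, limma adjusted p = 0.978) did not pass. Of the 6 sex-linked genes none passed limma and 1 was lower at an unadjusted p below 0.05, and 1 passed as lower without control replicate 2 or labelled knockout replicate 2 (camera adjusted p = 0.458). By *Xist* and Y-linked genes, control replicates 1 and 3 and labelled knockout replicate 2 were male and the other libraries female. With sex as a covariate, 4345 genes were higher and 3046 lower.

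Where no other figure is given, counts adjusted over the list alone equalled those over all genes. Camera with a preset correlation passed 14 of the 30 lists, 12 higher and 2 lower, and with an estimated correlation 2, the developmental transcription factors and the neuronal genes. Splits of the 6 libraries that mix both groups passed up to 18 lists by the same preset-correlation test. Each such split keeps part of the real difference between the groups, so these splits are no measure of chance for the lists.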

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

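Sex as a covariate and removal of GC content and transcript length were added after the data had been seen. Across the alternatives that kept all 6 libraries, the genes higher ranged from 3759 to 5332 and the genes lower from 3005 to 4974, and at least 3664 and 2765 of the original calls were kept in each. Of them, 1 reversed after removal of GC content and transcript length, and none elsewhere. Leaving out single libraries gave 3568 to 5666 higher, 2501 to 4006 lower, 4671 to 6058 changed at least 2-fold, and 12 to 16 lists passed. Of 273 named genes, 165 passed the test, 161 of these in every alternative with all libraries in which they were tested, and none reversed in any alternative. *Ring1* stayed higher and *Rnf2* stayed uncalled in all alternatives, whereas *Eed* was at −0.385 (limma adjusted p = 0.192) after removal of GC content and transcript length, and between −1.01 and −0.673 when single libraries were left out; the cause was not tested. With an estimated correlation 2 lists passed camera in place of 14. Merkel cell, germline and Schwann cell genes lost the call although their estimated correlations (−0.01, −0.00915 and −0.0583) lay below the preset 0.01. For these lists a higher correlation is therefore not the cause. The other lists that lost the call had estimates above 0.01, and the cause was not tested further. The immediate early list turned from not passing to lower after removal of GC content and transcript length (camera adjusted p = 0.0314), and the cause was not tested.

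Libraries with the same replicate number did not deviate together (correlations 0.061, −0.0231 and 0.0216), so the numbers do not pair them. With the replicate block 4761 genes were higher and 3345 lower, 5459 changed at least 2-fold, and 13 lists passed, without the mesenchymal transition list (camera adjusted p = 0.0512). Of the named genes that had not passed, 11 then did, among them *Lor* (log2 change 0.81, limma adjusted p = 0.041) and *Cd74* (0.68, limma adjusted p = 0.0494). The edgeR and DESeq2 alternatives were planned only for recovered whole reads and were not run. Low genes are limited by depth, with 1 read worth up to 1.31 normalized counts.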

Other observations

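The test of swapped labels and the test of other cell types below were chosen only after the results were seen, as were the removal of GC content and transcript length, the gene families and the single genes named here outside the lists. Among 268 families of at least 8 tested genes that share the start of their symbol, replication-linked histone cluster genes stood out, with 52 of 63 lower by limma, none higher (0 also at an unadjusted p below 0.05) and a median log2 change of −2.22 (one-sided Fisher's exact test against all tested genes, adjusted p = 7.79e-30). Genes of the Mcm root, mostly subunits of the replication helicase and its partners, fell for 8 of 10 (adjusted p = 0.000888). Zinc-finger genes with the Zfp root were lower for 147 and higher for 30 of 374 (median −0.51, adjusted p = 7.27e-28), and lower for 180 and higher for 22 with quantile normalization. In the other direction, 13 of 18 tetraspanin genes rose and none fell by limma, with 0 lower at an unadjusted p below 0.05 (median 0.97, adjusted p = 0.000184), and solute carriers rose for 106 and fell for 37 of 302 (adjusted p = 6.84e-07). All 8 tested Pax genes and 9 of 10 Nkx genes, developmental regulators, were higher. These counts were 6 and 9 with quantile normalization, and 7 and 7 after removal of GC content and transcript length. Many of these Pax and Nkx genes also stand in the list of developmental transcription factors, so the results overlap. As in that list, genes near 0 in controls were tested only where labelled knockouts were high. Genes are not independent replicates in these tests.

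At the imprinted *Igf2*-*H19* pair on chromosome 7, which are oppositely imprinted, both members changed, with *H19* falling from 82069 ± 10463 to 49460.2 ± 2827 (log2 change −0.72 ± 0.13) and *Igf2* rising from 20029 ± 5323 to 41941 ± 6043 (log2 change 1.10 ± 0.21). The basal keratins *Krt5* and *Krt14* fell from 202722 ± 43238 to 108256 ± 6531 and 68319.9 ± 17901 to 37295 ± 4222, a smaller change than that of *Krt15*.

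No other of the 10 splits of the 6 libraries into 3 and 3 gave as many genes. The real split gave 4726 higher and 3516 lower genes and 5425 with at least a 2-fold change. Any other split gave at most 1, 1 and 2, so in each case 1 split of 10 was as large. Every other split mixes both groups, so their difference enters the spread within each side and leaves few genes to call. These gene counts are therefore no measure of chance. For lists passed by camera, 4 of the 10 splits reached the real 14, and the highest other reached 18, although each of these other splits keeps part of the real difference between the groups. With 10 splits a share under 0.05 cannot be had. The split by sex gave 1 gene in each direction, but it also mixes both groups and so does not measure the effect of sex.

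*Ring1*, a gene that the labels call deleted, was higher in the libraries labelled triple knockout. A swap of both groups would place the *Eed* change on the wrong side, and *Eed* had a log2 change of −0.8217 with an SE of 0.212 and stayed below 0 in every alternative (−1.01 to −0.385, the last after removal of GC content and transcript length, which ended the call), whereas *Ring1* goes the way a swap would give, so that from the targeted genes alone a swap and correct labels cannot be told apart. Genes that Polycomb is known to repress ran mostly the way the labels say, with *Cdkn2a* rising from 0.329 ± 0.5698 to 171 ± 12.7, 85 of 94 developmental transcription factors higher and 2 lower, and 21 of 38 Hox genes higher and 7 lower, which leans against a swap as far as that known role holds here. Reads from neighbouring genes remain open, because the 6 tested genes within 25 kb had a median log2 change of 0.887 with an interquartile range of 0.804, between *Rxrb*, which did not pass (354 ± 31.6 against 283 ± 53.1, limma adjusted p = 0.21), and the class I histocompatibility gene *H2-K1*, which rose from 287 ± 114 to 1900.3 ± 286. A low or absent *Ring1* in the control genotype, RNA from an allele that makes no protein, and a rise of the gene itself when Polycomb repression is lost stay open as untested possibilities, since the labels name the control genotype only as control.

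Developmental transcription factors of other tissues rose for 85 of 94 genes. Fibroblasts, vessels, blood cells, muscle or fat carried over through the EpCAM sort would raise their own markers. The upper quartile of 91 such markers was 0.657, against a lower quartile of 2.59 for the transcription factors. It was 0.469 without control replicate 1 and 1.003 without control replicate 3. This comparison decides nothing, since the markers' median control level of 93.1, against 6.86 for the factors, would hide a small share of such cells. Abundant fibroblast genes moved apart, since *Col1a1* did not pass (4968 ± 4651 against 3826 ± 935, limma adjusted p = 0.981), *Postn* fell from 15743 ± 3290.2 to 902 ± 258 and *Fstl1* rose from 2125 ± 1206 to 13347 ± 1493, with 5 higher and 4 lower of 20 in that list. GC content and transcript length are argued against as the whole cause, since 80 of the 85 still rose after their removal (median log2 change 4.69 before and 4.19 after). Loss of Polycomb repression in the epidermal cells is a candidate explanation and remains a hypothesis. The cell types above and Merkel cells, melanocytes and Schwann cells stay open as sources, because how far the sort removed them was not measured.

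Of 63 histone cluster genes 52 were lower by limma, none were higher and the others did not pass. After removal of GC content and transcript length 50 of the 52 still fell (median −2.36 before and −2.57 after), which argues against these as the whole cause. As a set the 10 replication-independent histone genes did not fall as far, although 3 were lower and 1 higher (median −0.09, interquartile range 0.89). The difference in medians of 2.13 is what less expression of genes used in DNA replication could give, and 37 of 42 proliferation genes were also lower. Reads shared between histone copies, and a different yield of RNA without a poly(A) tail between libraries, were not tested and may contribute.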
